A study of Mus musculus with 3 samples.

How the data were processed

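Single-cell suspensions of whole mouse brain with the dura mater, the outer membrane around the brain, were profiled by droplet-based 3' RNA sequencing on the 10x Chromium platform with version 3 library chemistry, per the labels' protocols. Female C57BL/6J mice of 9 weeks received an intraperitoneal injection of phosphate-buffered saline (PBS) or 2.5 mg/kg lipopolysaccharide (LPS), a bacterial endotoxin, and tissue was taken at 12 h, per the labels. The series holds 3 libraries. The control library pooled 4 mice, and LPS libraries 1 and 2 pooled 3 mice each, per the labels' protocols. The deposited counts are whole-number UMI (unique molecular identifier) counts per gene and cell barcode, not normalized, which the authors made with Cell Ranger against the mm10 mouse genome, per the submitters' processing notes; the Cell Ranger version and the annotation are not given in the sources used here. A further 2 combined tables of the whole series hold the same barcodes with lower totals and were not used here. Why their totals are lower was not tested.

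The control library held 5256 barcodes, LPS library 1 held 4162 and LPS library 2 held 6428, the same numbers of cells as the labels give. Cells with 500 or more UMIs, 200 or more detected genes and 10% or less mitochondrial UMIs were kept. Doublets were scored per library against 2 simulated doublets per cell, after the Scrublet method, and the highest-scoring cells were removed, at a rate of 0.8% per 1000 barcodes of the library (196, 124 and 307 cells in the control library, LPS library 1 and LPS library 2). This left 13743 cells. The kept cells of all libraries were log-normalized to 10000 UMIs and clustered together on 2000 variable genes and 30 principal components with 15 nearest neighbours and the Leiden algorithm at resolution 1, which gave 38 clusters. Clusters were named "-like" from 28 marker lists. A cluster took the name of its best-scoring list when that score was 1 or more, at least 3 of its markers were 2-fold higher than in other cells, the best list of an unrelated class scored under 0.7 times as high, and neither its leading gene nor most markers among its top 10 genes belonged to an unrelated class. Among related classes, the list with most markers in the top 10 gave the name, and clusters of low UMI number with no marker there stayed unnamed. This scoring rule was set after the matrices had been read, while the markers were fixed earlier. A total of 6 clusters (11.2% of control cells, 9.08% of LPS library 1 and 7.93% of LPS library 2) stayed unnamed, and the others formed 18 classes. No deposited cell annotation was used here.

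The library, a pool of mice, was the replicate. Raw counts were summed per library over the cells of a class and tested in each of the 12 classes with 30 or more cells in every library, with edgeR's quasi-likelihood test after TMM scaling and filterByExpr. All edgeR tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The fit had 1 residual degree of freedom, from the 2 LPS libraries, moderated across genes, and the lone control library was assumed to vary like the LPS libraries. The p-values therefore measure the spread between these pools, and no control replicate tested that assumption. CPM (counts per 1000000) within a class use TMM-scaled library sizes. Differences in response between microglia-like and border-associated macrophage-like cells were tested as an interaction of class and treatment with the library as a block. Class shares were tested with the same edgeR method on cell numbers, without TMM. A total of 26 gene lists were tested with camera on voom values at an inter-gene correlation of 0.01, and their members were also adjusted over the list alone.

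The named genes followed a fixed rule: the 12 largest rises and 12 largest falls in log2 fold change in microglia-like cells, 6 and 6 in border-associated macrophage-like cells and 4 and 4 in each of the 10 other tested classes, among called genes with at least 50 CPM in the higher group and both LPS libraries on the same side of the control. The rule added the 3 members of each list with the largest change among those with 20 CPM or more in a group, and Il10, Il10ra, Il10rb, Tnf, Il1b, Il6, Stat3, Socs3, Tlr4, P2ry12 and Tmem119. Predicted genes, mitochondrial, ribosomal, immunoglobulin and T cell receptor genes and members of lists of RNA from other cells were left out of the ranking. Where a gene had 0 UMIs in the control library, the fold is a lower bound against a floor of 3 counts in that library, or, for falls to 0, over the LPS group; with 1 to 3 control counts the ratio is given with its 95% counting interval. Shares carry exact binomial 95% intervals, and a share of 0 carries the limit that 3 counts of the total allow. These intervals and limits cover counting error only.

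The samples' groups, the tests, the gene and marker lists, the rule for naming genes and all alternatives but 2 were fixed before the data were examined, but the rule that names clusters was not. The alternatives were DESeq2, limma-voom with a prior count of 2, no TMM, no count filter, no cell filter, 5% mitochondrial UMIs, no doublet removal, Leiden resolutions 0.5 and 2, clustering each library alone, thinning cells to 1000 UMIs, subtracting the library-wide profile, other set tests, TMM over classes, shares without neutrophil-like cells, and leaving out each LPS library. Chosen after seeing the data were an adjusted p under 0.1 for microglia-like cells and a fit of the immature neutrophil-like cluster alone.

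The test was tested on simulated data with 200 changed genes drawn from the real means and library sizes. Of the changed genes in simulated microglia-like cells (10278 genes), it recovered 28.4% at 2-fold, 91.0% at 4-fold and 98.5% at 8-fold, with 13 false calls. In simulated border-associated macrophage-like cells (9265 genes) the shares were 8.96%, 74.6% and 89.4%, with 10 false calls. For classical monocyte-like cells (10855 genes) they were 14.9%, 68.7% and 92.4%, with 8 false calls. For T cell-like cells (9728 genes) they were 31.3%, 85.1% and 97.0%, with 3 false calls. In the simulation every gene of a class had the same spread, while in the real data the spread also varied between genes. These shares may therefore overstate how many real changes of such sizes were called. The files give gene symbols without coordinates. Of 28692 symbols, 27337 matched GENCODE M21, the annotation of GRCm38 (mm10), from which coordinates were taken. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.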

Results

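The series asks how brain immune cells respond to a peripheral endotoxin challenge, with IL-10, an anti-inflammatory cytokine, in its title. Whole brain and dura of control mice and of mice 12 h after LPS were profiled as single cells in 1 control library (a pool of 4 mice) and 2 LPS libraries (pools of 3 mice). Total depth was 36488985 UMIs in the control library, 42563910 in LPS library 1 and 66730179 in LPS library 2, with medians of 5043, 7089.5 and 8612.5 UMIs per barcode. After filtering, 4467 control cells, 3611 cells of LPS library 1 and 5665 cells of LPS library 2 remained, with medians of 5217, 7839 and 8867 UMIs. Nearly all named classes were leukocytes; fibroblast-like cells numbered 5, 5 and 4, and the labels used here state no sort.

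The mix of immune cells differed between control and LPS libraries. Classical monocyte-like cells, blood-derived phagocytes, made up 2.22% of control cells (exact 95% interval 1.80 to 2.69%) against 18.0% (16.7 to 19.3%) and 28.7% (27.5 to 29.9%) of cells in the LPS libraries, a log2 change of 3.40 (SE 0.75, adjusted p = 0.00113). This control share and fold depend on how control cells were clustered: with no doublet removal 0 control cells took this name (log2 change 12.95) and at Leiden resolution 0.5 only 1 did (9.81). Border-associated macrophage-like cells, the resident macrophages of the brain's borders, fell from 18.0% (16.9 to 19.2%) to 4.04% (3.42 to 4.74%) and 2.86% (2.44 to 3.33%), a log2 change of -2.38 (SE 0.60, adjusted p = 0.0032). Neutrophil-like cells rose from 1.79% to 7.81% and 7.5%. Migratory dendritic cell-like cells rose from 0.269% to 3.66% and 4.92%, and granulocyte-monocyte progenitor-like cells from 1.19% to 3.96% and 4.57%. B cell-like cells fell from 7.48% to 0.803% and 0.177%, and conventional dendritic cell 2-like cells from 5.40% to 0.637% and 0.212%. The sizes of these changes moved with the setting. For B cell-like cells the log2 change was -3.99, but -1.59 with 5% mitochondrial UMIs or less, -2.32 with no cell filter, -2.51 at Leiden resolution 0.5 and -1.91 with each library clustered alone (adjusted p = 0.155). For conventional dendritic cell 2-like cells it was -3.72, but -2.82 with 5% mitochondrial UMIs or less, -2.61 with no doublet removal, -2.35 at Leiden resolution 2 and -1.09 with each library clustered alone (adjusted p = 0.431). For neutrophil-like cells it was 2.09, but 3.58 with no cell filter and 3.14 at Leiden resolution 2. It was 1.63 with 5% mitochondrial UMIs or less and 1.93 with each library clustered alone (adjusted p = 0.194). In all, the shares of 7 of 19 classes (18 named, and the unnamed clusters as 1) passed the edgeR test with Benjamini-Hochberg adjustment. Microglia-like cells, the macrophages of the brain parenchyma, took 12.5%, 12.8% and 9.43% of cells, a difference that did not pass the test (log2 change -0.17, SE 0.62, adjusted p = 0.83), although with 5% mitochondrial UMIs or less they fell (log2 change -0.98, adjusted p = 0.0167). Unnamed clusters held 11.2%, 9.08% and 7.93% of cells. Shares are relative, so a gain of one class lowers the others. At Leiden resolution 2 no class passed the edgeR test, with log2 changes of 3.30 for classical monocyte-like and -2.39 for border-associated macrophage-like cells (adjusted p = 0.0682 for each), against 13 with 5% mitochondrial UMIs or less. With each library clustered alone, migratory dendritic cell-like cells passed, with 3 classes that were absent from a library, while classical monocyte-like and border-associated macrophage-like cells did not (log2 changes of 2.71 and -2.24, adjusted p = 0.0898 for each). The rise of granulocyte-monocyte progenitor-like cells (log2 change 1.84, adjusted p = 0.0461) did not pass with no cell filter (log2 change 0.80, adjusted p = 0.258), at Leiden resolution 0.5 (1.17, adjusted p = 0.207) and without neutrophil-like cells (1.93, adjusted p = 0.0504). Nor did it pass with each library clustered alone (2.05, adjusted p = 0.180).

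**Figure D1:**
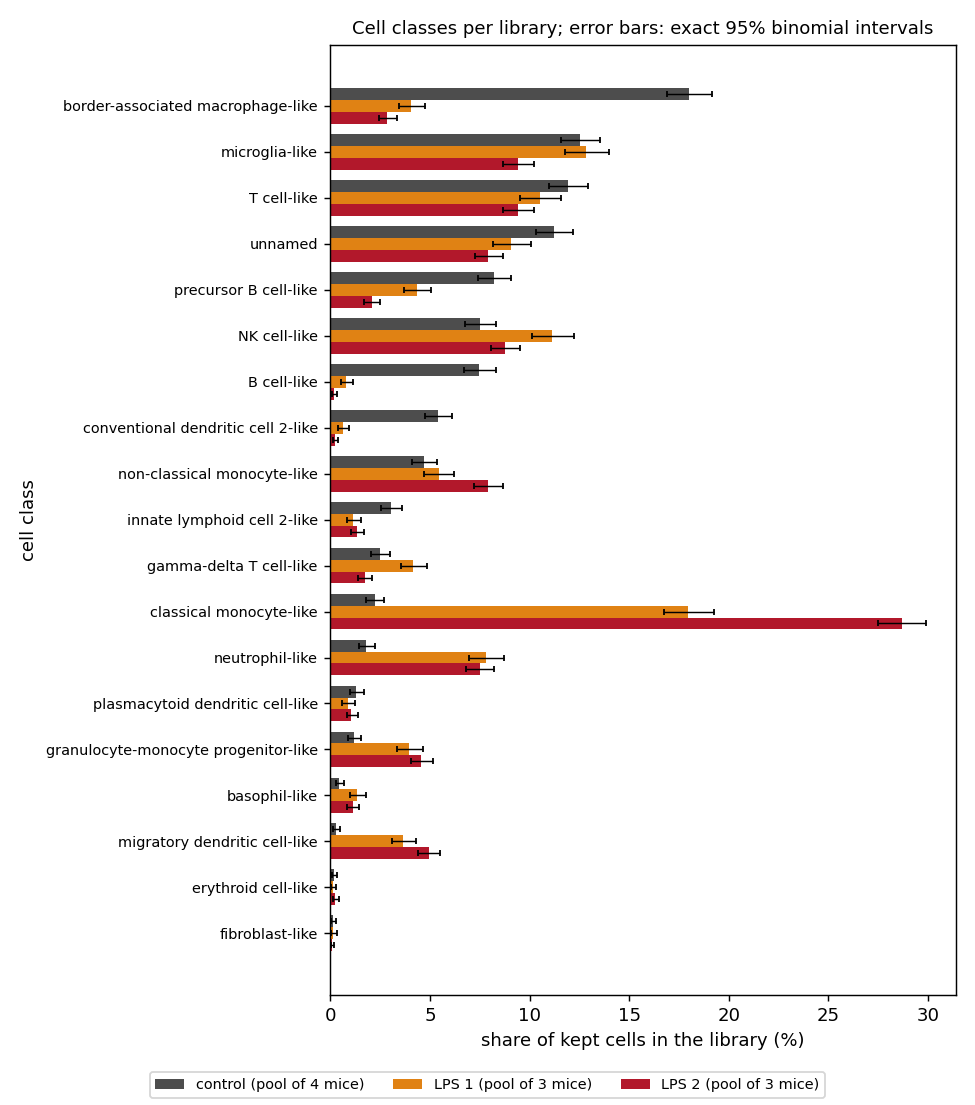
Share of kept cells (%, horizontal axis) that each class took in each of the 3 libraries (bars), with exact 95% binomial intervals as error bars. Classical monocyte-like cells went from 2.22% in the control library to 18.0% and 28.7% in the LPS libraries, and border-associated macrophage-like cells from 18.0% to 4.04% and 2.86%.

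In microglia-like cells (560 control cells, 464 and 534 LPS cells), LPS was accompanied by a rise of Mt2, Ccl5 and most measured interferon-response genes and a fall of P2ry12 and Tmem119. Mt2, a metal-binding stress protein, rose 539-fold, from 2.07 CPM (counts per 1000000) to 1146 and 1091 CPM (log2 9.04, SE 0.34, adjusted p = 0.0297, edgeR). Ccl5, a chemokine that attracts lymphocytes and monocytes, rose 59.8-fold, from 45.3 to 1894 and 3526 CPM (log2 5.90, SE 0.55, adjusted p = 0.0481). P2ry12, the purinergic receptor used to recognise resting microglia, fell from 2882 to 650 and 394 CPM (log2 -2.46, SE 0.32, adjusted p = 0.0494), and Tmem119, another microglial marker, from 1644 to 574 and 512 CPM (log2 -1.60, SE 0.18, adjusted p = 0.0494). Of 10278 tested genes, 118 rose and 54 fell. Control cells lay in cluster 5, as did 95 cells of LPS library 1, while cluster 2 held the other LPS cells apart from 2.

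Among the largest rises, Zbtb16, a zinc-finger transcription factor, was at least 103-fold higher, with 0 control UMIs against 102 and 111 CPM (adjusted p = 0.0297). Cxcl2, a neutrophil-attracting chemokine, rested on 1 control count and had a ratio of 550 (95% counting interval 98.5 to 21759). In LPS library 1 it stood at 227 CPM in cluster 5, that of the control cells, and 166 CPM in cluster 2 (without TMM). Lcn2 went the same way (547 and 300 CPM), while Mt2 (32.8 and 1355 CPM) and Il1rn (41.6 and 295 CPM) went the other way. Il1rn, the antagonist of the IL-1 receptor, had 2 control counts and a ratio of 417 (115 to 3447), and AA467197 a ratio of 96.2 (26.4 to 798). Cd300lf, an immune receptor, rose 137-fold (206 and 458 CPM, log2 7.07, SE 0.86, adjusted p = 0.0494) and Ehd1, of endocytic recycling, 87.8-fold. Klf9, a glucocorticoid-responsive transcription factor, rose 72.7-fold, the scavenger receptor gene Msr1 72.3-fold (114 and 186 CPM), Oasl1 56.9-fold and Mnda 51.7-fold. The largest falls were in Thrsp (log2 -3.55, SE 0.46, adjusted p = 0.0494; 10.3 and 4.04 CPM after LPS), Npnt (-3.27), Hacd4 (-3.11; 8.95 and 4.49 CPM), Bank1 (-3.08; 11.2 and 6.74 CPM), Fam110a (-3.06), Garnl3 (-2.84), Whrn (-2.83; 19.7 and 12.1 CPM), Hist1h2bc (-2.71), Arap3 (-2.48), the iron exporter gene Slc40a1 (-2.42) and Klhdc8b (-2.42).

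**Figure D2:**
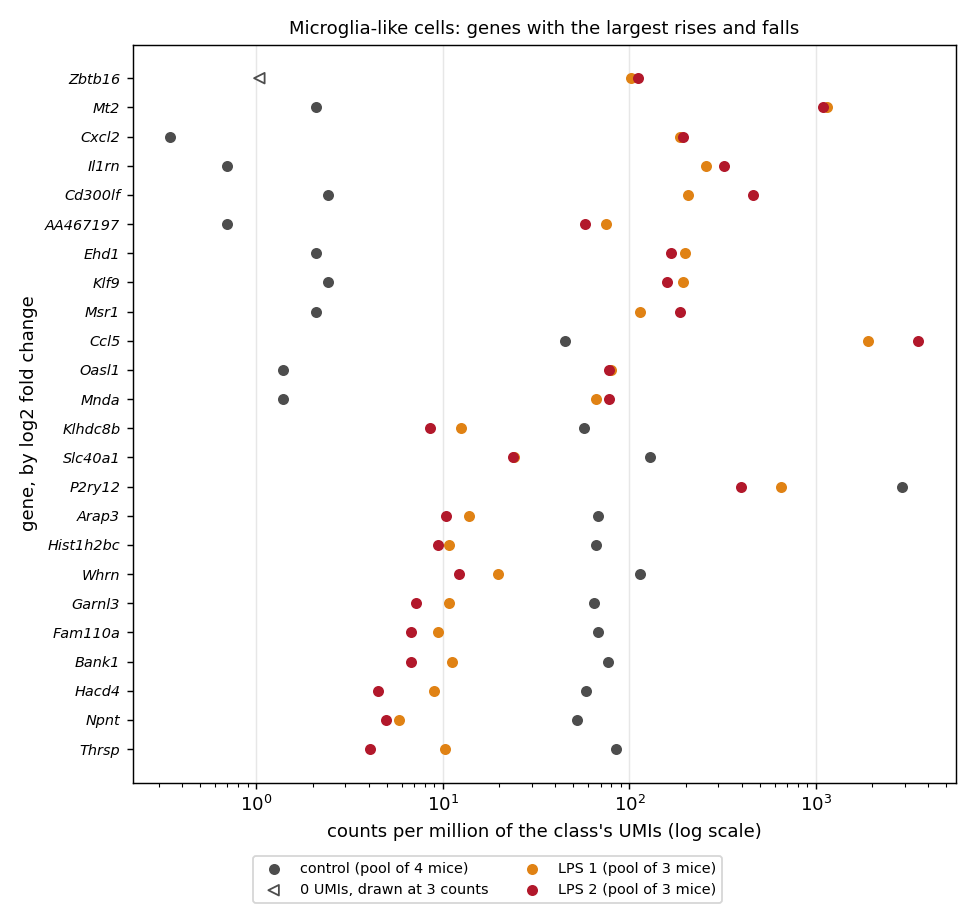
Expression in microglia-like cells (CPM, log axis) of the 12 genes with the largest rises and the 12 with the largest falls, each point 1 library; the triangle marks 0 UMIs, drawn at 3 counts, which lies above genes with 1 or 2 control counts. Only genes with both LPS libraries on the same side of the control were eligible; P2ry12 stood at 2882 CPM in control and 650 and 394 CPM in LPS.

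Interferon-response genes rose together in microglia-like cells: 13 of 18 measured members rose and none fell, 18 when adjusted over the list alone, including Rsad2 (45.0-fold) and Irf7 (26.8-fold). As a ratio of microglia-like to library-wide CPM, 9 of the 13, Oasl1 among them, stood above the highest ratio of neutrophil and monocyte markers that control microglia-like cells lack, but Rsad2 and Irf7 did not. Of 13 chemokines, 4 rose (11 adjusted over the list alone); Cxcl10 stood at 5.88, 568 and 203 CPM without passing (adjusted p = 0.058). Cxcl13 stood at 0, 0 and 138 CPM. Of 11 genes of endotoxin sensing and the acute phase, 7 rose (9 rose and 2 fell over the list alone), among them Lcn2 (69.5-fold, adjusted p = 0.0297), also a neutrophil gene. Saa3 was at 2.07, 334 and 1270 CPM (adjusted p = 0.0596). Of 9 glucocorticoid-response genes, 5 rose (7 over the list alone), Zbtb16, Klf9 and Dusp1 (18.6-fold) among them. Of 18 homeostatic microglia genes, 4 fell and none rose (15 fell over the list alone), with Gpr34 at 1936, 242 and 90.3 CPM (adjusted p = 0.0584). Of 15 NF-kB targets 2 rose (10 over the list alone), including its inhibitor gene Nfkbia (7.58-fold, adjusted p = 0.0401). Of 10 genes of IL-10 and STAT3 signalling 3 rose (7 over the list alone), including Socs3 and Nfil3 (12.2-fold). These 7 lists, and those of MHC class I, lymphocyte activation, pro-inflammatory cytokines, complement, apoptosis, glycolysis, neutrophil RNA and B cell RNA, passed the camera test at a preset correlation (15 of 24). None passed otherwise: adjusted p = 0.602 with an estimated correlation for each of the 15, and the rotation test fry passed 0 lists.

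In microglia-like cells the complement genes C4b (11.2-fold) and C5ar1 (5.28-fold) rose among 8 measured (5 over the list alone). Of 9 lymphocyte activation genes 2 rose, Socs3 and Cd44 (7 rose and 1 fell over the list alone), and of 11 apoptosis and p53 genes 2 rose, Cdkn1a (17.7-fold) and Fas (15.9-fold), with 4 and 1 over the list alone. Of 9 adhesion genes, Cd44 (10.2-fold) rose and Selplg (log2 -1.42) fell, with 2 and 2 over the list alone. Of 13 immediate early genes often raised by tissue dissociation, Dusp1 and Ier2 (11.0-fold) rose (2 rose and 1 fell over the list alone), and of 14 lysosomal genes Cd63 (3.49-fold) rose (6 rose and 2 fell over the list alone). Of 8 TNF and IL-1 receptor genes only Il1rn rose (1 over the list alone). No member passed among 14 genes of disease-associated microglia (3 rose and 4 fell over the list alone), 11 of MHC class I (5 rose), 10 pro-inflammatory cytokines (4 rose), 13 of glycolysis (4 rose), 7 of MHC class II, 9 of cholesterol handling and 8 of the cell cycle (0 each over the list alone). For disease-associated genes the mean was 0.15 on the log2 scale and the median -0.06, and the camera test pointed down (adjusted p = 0.931, adjusted p = 0.941 with an estimated correlation). Adhesion genes likewise had a mean of 0.33 and a median of 0.03 with a downward camera test (adjusted p = 0.759), and the 3 measured IL-10 ligand and receptor genes a mean of 0.59, a median of -0.78 and a downward test (adjusted p = 0.344), with 0 called and, over the list alone, 1 higher and 2 lower. Among genes of other cells, 1 of 6 neutrophil genes was called (Lcn2), and S100a8 stood at 19.7, 432 and 90.3 CPM without passing (adjusted p = 0.126). The B cell gene Ighm did not pass either, at 264, 71.6 and 31.0 CPM (adjusted p = 0.0747), with 0 of 4 B cell genes called (2 fell over the list alone). Of brain parenchyma genes 2 were measured and 0 called, and no erythroid gene was measured.

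The number of called genes in microglia-like cells depended on the method, from 0 without a count filter or at Leiden resolution 0.5, and 5 with limma-voom, to 2312 with each library clustered alone. Without TMM, which shifted the median log2 change by -0.17, 523 genes rose and 856 fell in place of 118 and 54.

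In microglia-like cells the LPS libraries differed less from each other than each did from the control library. The SD of the log2 ratio of LPS library 1 to LPS library 2 over 10278 genes was 0.531, and 6.37% of genes differed over 2-fold between them, against 24.2% and 23.8% between each LPS library and the control. Of the 172 called genes, 105 had the smaller change in LPS library 1. More cells of LPS library 1 lay in clusters made up mostly of control cells: 10.3% of its cells against 1.09% in LPS library 2. Among microglia-like cells this was 20.5% (exact 95% interval 16.9 to 24.4%) against 0.375% (0.0454 to 1.35%), and among border-associated macrophage-like cells 38.4% (30.4 to 46.8%) against 0.617% (0.0156 to 3.39%).

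**Figure D3:**
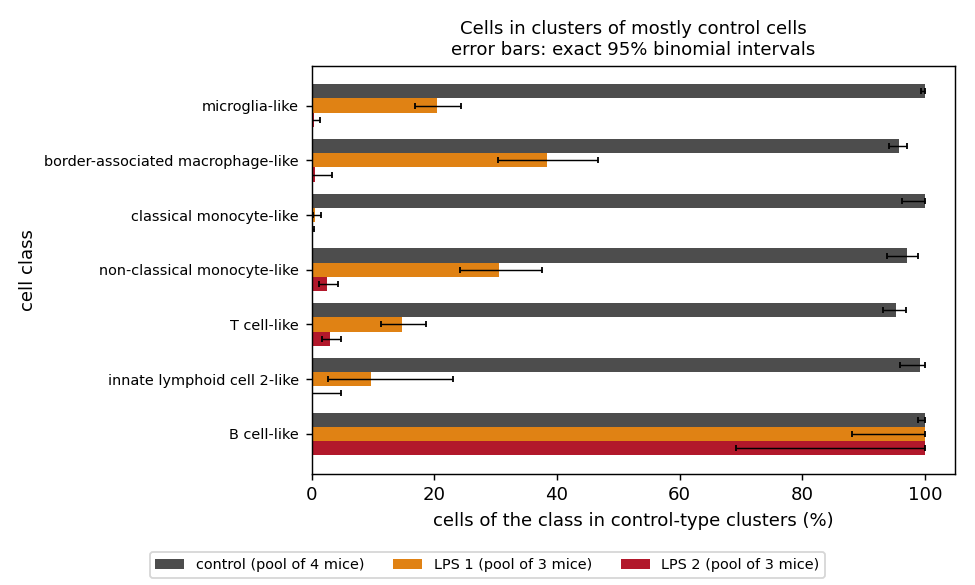
Share of each class's cells (%, horizontal axis) that lay in clusters with at least 70% control cells, per library (bars), with exact 95% binomial intervals as error bars; B cell-like cells formed a single such cluster. In LPS library 1 the share was 38.4% for border-associated macrophage-like and 20.5% for microglia-like cells, against 0.617% and 0.375% in LPS library 2.

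Border-associated macrophage-like cells (804 control cells, 146 and 162 LPS cells) gained transcripts of Csf3, Saa3 and chemokines. Csf3, the gene of granulocyte colony-stimulating factor, was at least 965-fold higher, from 0 control UMIs to 595 and 610 CPM (adjusted p = 0.00855, edgeR). Saa3, an acute-phase protein gene, rose 7725-fold, from 3.74 to 19289 and 38532 CPM (log2 12.89, SE 0.77, adjusted p = 0.0149), and Ccl5 rose 313-fold, from 33.9 to 9815 and 11379 CPM (log2 8.29, SE 0.25, adjusted p = 0.00314). Irg1, whose enzyme makes itaconate, was at least 375-fold higher, Ccl17 at least 90.1-fold (75.7 and 36.7 CPM) and Lipg at least 85.4-fold (68.9 and 37.7 CPM). Il1rn, on 1 control count, had a ratio of 5962 (1069 to 235570; 1545 and 833 CPM). Gpr34 fell from 249 to 38.3 and 17.3 CPM (log2 -3.13, SE 0.45, adjusted p = 0.0387). The next falls were in St8sia4 (-3.08; 31.4 and 14.3 CPM after LPS), Lpar6 (-3.01), Pxdc1 (-2.83), Cep68 (-2.66; 10.7 and 6.12 CPM) and Ggt5 (-2.51). Of 9265 tested genes 300 rose and 36 fell. Control cells lay mostly in cluster 3 and LPS cells mostly in cluster 23. Cluster 36, of low-UMI cells, was all control. In LPS library 1, Csf3 stood at 2.17 CPM (1 UMI) in the 56 cells of cluster 3 and 835 CPM in cluster 23 (without TMM). Saa3 stood at 3088 and 25597 CPM in these clusters, against 4.07 CPM in control cells of cluster 3. Ccl5 stood at 1870 and 12877 CPM, and the marker Mrc1 at 3251 and 1628 CPM. No test was run on these values.

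By list, 12 of 18 interferon-response genes rose in border-associated macrophage-like cells (18 adjusted over the list alone), with Rsad2 54.4-fold and Isg15 38.5-fold higher. Of 16 NF-kB targets 9 rose (14 over the list alone), including Sod2 (63.9-fold) and Tnfaip3 (33.0-fold), and of 13 chemokines 7 rose (13 over the list alone), Cxcl2 by 825-fold. Of 9 pro-inflammatory cytokines 5 rose (7 over the list alone): beside Csf3, Il1a rose 42.0-fold, Il1b 9.03-fold (adjusted p = 0.0299) and Tnf 6.72-fold (adjusted p = 0.0331). In microglia-like cells Tnf stood at 9.68, 46.5 and 122 CPM (adjusted p = 0.0899) and Il1b at 10.4, 114 and 16.6 CPM (adjusted p = 0.252), so that neither passed. Of 10 IL-10 and STAT3 signalling genes 4 rose (7 over the list alone), of 12 endotoxin and acute-phase genes 7 (10 rose and 1 fell over the list alone), of 13 glycolysis genes 3 (7 over the list alone) and of 11 MHC class I genes 2 (8 over the list alone). The camera calls on these 8 lists did not hold with an estimated correlation, where adjusted p = 0.403 (interferon, NF-kB, chemokines, IL-10 and STAT3, acute phase) or adjusted p = 0.474 (cytokines, glycolysis, MHC class I) with an estimated correlation. In the remaining lists, 5 of 10 glucocorticoid-response genes rose (7 rose and 1 fell over the list alone), 3 of 11 apoptosis and p53 genes (7), 3 of 11 lymphocyte activation genes (9) and 3 of 11 adhesion genes (4). So did 2 of 9 complement genes (2; Cfb 23.2-fold), 2 of 8 TNF and IL-1 receptor genes (5), 2 of 14 immediate early genes (4 rose and 1 fell) and, among 14 disease-associated genes, Spp1 (6 rose and 2 fell). Of 15 homeostatic genes Gpr34 fell (6 over the list alone). None passed among genes of MHC class II (6 measured; 1 rose and 2 fell over the list alone), the lysosome (14; 3 and 1), cholesterol handling (10; 0), the cell cycle (8; 2 rose), the brain parenchyma (5; 0) and IL-10 ligand and receptors (3; 1 and 2). The median and mean had opposite signs for MHC class II (0.36 and -0.04), complement (-0.08 and 0.73), brain parenchyma (-0.32 and 0.01) and IL-10 ligand and receptor genes (-0.72 and 0.25). The camera test pointed against both for neutrophil RNA (-0.77 and -0.05, up; Lcn2 rose and Ltf fell of 7) and cholesterol handling (0.23 and 0.24, down). The B cell gene Ighm fell from 153 to 32.1 and 28.5 CPM (adjusted p = 0.0285) in this class. Leiden resolutions 0.5 and 2 gave 337 and 336 called genes, and the other settings between 633 (DESeq2) and 2123 (no count filter). Without TMM (median shift -0.29) 650 rose and 987 fell.

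The responses of both macrophage classes overlapped and also differed. Of 8908 genes tested in both, 69 rose in both classes, against 3.57 for independent lists (114 and 279 genes), and 2 fell in both, against 0.146 (42 and 31 genes). Simulated groups with no effect gave 0 in each direction in 20 draws. The simulation left out the effects and gave every gene the common spread of microglia-like cells. With no effects few genes can pass in either class, so these draws cannot show how many of the 69 come from the shared control. The expectation for independent lists leaves out the single control library that both classes share. Part of the excess may therefore come from the shared control. A test of the difference itself called 264 of 10903 genes, 167 with the higher log2 change in border-associated macrophage-like cells and 97 with the higher change in microglia-like cells. Il1a differed by 4.59 (SE 0.54, adjusted p = 0.0012), with 0.832, 41.3 and 28.5 CPM in border-associated macrophage-like cells and 57.8, 109 and 85.3 CPM in microglia-like cells. Gpr65, a proton-sensing receptor gene, differed by -5.21 (SE 0.34, adjusted p = 1.71e-05), from 18.3 to 340 and 484 CPM in microglia-like cells and from 167 to 91.1 and 105 CPM in border-associated macrophage-like cells. Without a count filter 547 genes differed, without doublet removal 566 and at Leiden resolution 2 462; without TMM the split was 138 and 152 genes.

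In classical monocyte-like cells (99 control, 649 and 1625 LPS cells) chemokine and interferon genes rose and Cx3cr1 fell. AA467197 was at least 996-fold higher (0 control UMIs, 2636 and 2401 CPM), Ccl12, a monocyte-attracting chemokine, at least 234-fold, the protease inhibitor gene Timp1 at least 224-fold (703 and 433 CPM) and Irg1 at least 207-fold. Cx3cr1, the fractalkine receptor, fell from 327 to 5.35 and 4.27 CPM (log2 -6.11, SE 0.29, adjusted p = 3.17e-06), with Dgkg (-6.39), St8sia4 (-5.45) and Hpgd (-5.40) also lower. After LPS, Dgkg stood at 1.31 and 0.237 CPM (11 and 5 UMIs), St8sia4 at 5.71 and 2.18 CPM and Hpgd at 2.85 and 1.66 CPM. Without LPS library 2, with a prior count, the log2 change was -4.94 for Dgkg in classical monocyte-like cells, -4.74 for St8sia4 in classical monocyte-like cells and -4.82 for Hpgd in classical monocyte-like cells. Of 18 interferon genes 16 rose, of 11 chemokines 10 rose, and of 8 MHC class II genes 6 fell. Of 7 neutrophil genes 3 rose (mean log2 2.14, camera adjusted p = 0.00372, adjusted p = 0.478 with an estimated correlation). Among 10855 tested genes 1163 rose and 815 fell, and without TMM 839 rose and 1706 fell (median shift -0.39). Nearly all LPS cells lay in clusters 1 and 29 and all control cells in cluster 31.

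Non-classical monocyte-like cells (209 control, 196 and 448 LPS cells) had at least 6877-fold higher Saa3 (0 control UMIs, 5139 and 22831 CPM, adjusted p = 0.038), at least 30.9-fold higher Marco, a scavenger receptor gene. Cd38 had a ratio of 131 on 3 control counts (44.7 to 636; 139 and 323 CPM after LPS), and Sdc4 was 108-fold higher (425 and 745 CPM). G0s2 (log2 -3.89; 14.4 and 5.02 CPM after LPS), Dusp5 (-2.89), Mdm1 (-2.55; 18.0 and 11.0 CPM) and Smc6 (-2.44; 111 and 70.5 CPM) fell. Here 93 genes rose and 10 fell of 8996, but none passed without TMM (1786 at an unadjusted p under 0.05, edgeR), while DESeq2 called 257 and 54. Of 5 neutrophil genes 2 rose (mean log2 3.65) and of 4 B cell genes 1 fell (mean log2 -3.14). LPS cells lay mostly in cluster 8 and control cells in cluster 19.

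Neutrophil-like cells (80 control, 282 and 425 LPS cells) had at least 2690-fold higher Cxcl2 (0 control UMIs, 3237 and 2872 CPM), at least 485-fold higher Upp1, at least 339-fold higher Ccl3 and a Saa3 ratio of 5565 (999 to 219810) on 1 control count. All 18 interferon genes and all 8 measured pro-inflammatory cytokines rose, Il1b by 42.1-fold. Elane, a protease gene of immature granulocytes, fell from 5122 to 740 and 239 CPM (log2 -3.39, SE 0.58, adjusted p = 0.00667), and Mgl2 (-4.30), Myb (-3.70) and Gstm1 (-3.24) fell as well. After LPS, Mgl2 stood at 5.86 and 1.36 CPM, Myb at 12.6 and 1.64 CPM and Gstm1 at 29.0 and 13.4 CPM. Without LPS library 2, with a prior count, the log2 changes were -2.79 for Elane in neutrophil-like cells, -3.46 for Mgl2 in neutrophil-like cells, -2.80 for Myb and -2.76 for Gstm1. Immature cells of cluster 22 made up 74 of 80 control cells but 91 of 282 and 91 of 425 LPS cells, and without a cell filter Elane (1.69) and Mgl2 (0.40) had changes of the opposite sign. In all 1019 genes rose and 420 fell, and without TMM 519 and 1178 (median shift -0.64); without doublet removal 2118 rose and 1765 fell, and within cluster 22 alone, a fit added after seeing the data, 784 rose and 505 fell. Granulocyte-monocyte progenitor-like cells (53 control, 143 and 259 LPS cells) had at least 530-fold higher AA467197, at least 323-fold higher Ccl12, at least 218-fold higher Irg1 and at least 165-fold higher Sdc4. Prg2, an eosinophil granule gene, was at least 317-fold lower, and Bex6 (-5.33), AI839979 (-4.14; 6.30 and 4.10 CPM after LPS) and Myb (-3.83), a progenitor transcription factor, fell. All 7 neutrophil genes rose in that class (mean log2 4.73). There 1235 genes rose and 782 fell, and without TMM 1079 and 1660 (median shift -0.21).

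In gamma-delta T cell-like cells (111 control, 150 and 97 LPS cells) Il22 and Il17f rose, while of 2 measured pro-inflammatory cytokines on the fixed list 0 were called. Il22, a cytokine of the IL-10 family that acts on epithelia, was at least 1376-fold higher (0 control UMIs, 6897 and 6025 CPM), and Il17f at least 373-fold higher (1661 and 1840 CPM). Mt2 was at least 68.0-fold and Cxcl2 at least 45.5-fold higher (151 and 276 CPM), while Kcnc1 (log2 -2.99; 5.25 and 8.43 CPM after LPS), Rnase4 (-2.64), Coro2b (-2.53; 13.1 and 8.43 CPM) and the chemokine receptor gene Cxcr3 (-2.52) fell. NK cell-like cells (336 control, 402 and 497 LPS cells) had at least 141-fold higher Gzmf, a granzyme gene (62.9 and 331 CPM), at least 37.0-fold higher Mt2 (33.0 and 70.4 CPM), 94.5-fold higher Mt1 (136 and 305 CPM) and a Saa3 ratio of 154 (52.4 to 746; 66.8 and 354 CPM). Without LPS library 2, with a prior count, the log2 changes in NK cell-like cells were 6.16 for Gzmf, 5.24 for Mt2, 5.40 for Mt1 and 4.88 for Saa3. Cxcr3 (-3.27), Tsc22d1 (-3.04; 17.1 and 4.83 CPM after LPS), Cd7 (-2.96) and S100a4 (-2.90; 350 and 186 CPM) fell in NK cell-like cells. The balance of clusters also differed: NK cluster 6 held 57 control, 254 and 309 LPS cells and NK cluster 7, with Cd7 among its leading genes, 279, 148 and 188, and no test was run within them. T cell-like cells (533 control, 380 and 534 LPS cells) had ratios of 190 (52.3 to 1574) for Calca, a gene also on the marker list of innate lymphoid cells, and 193 (34.3 to 7652) for Mt2, with Mt1 163-fold (208 and 555 CPM) and Saa3 86.6-fold (61.8 and 191 CPM) higher. Calca stood at 152 and 73.2 CPM and Mt2 at 40.6 and 70.7 CPM in the LPS libraries. Cxcr6 (-2.34), Tesc (-2.21; 33.4 and 13.2 CPM after LPS) and Stap1 (-2.13) fell in T cell-like cells, and the fall of Jchain (-8.76) rested on 1 control cell that held 99.9% of 2636 UMIs. LPS T cell-like cells lay mostly in cluster 4 and control cells in clusters 13 and 25. Cluster 25, with Cxcr6 and Tesc among its leading genes, held 169 control cells and 33 and 6 LPS cells, and no test was run within it. Innate lymphoid cell 2-like cells (136 control, 41 and 76 LPS cells; cluster 27 in control and 30 in LPS) had at least 855-fold higher Mt1 (4442 and 1716 CPM), at least 93.0-fold higher Mt2 (522 and 148 CPM) and at least 56.9-fold higher Cxcl2 (324 and 86.7 CPM). Without LPS library 1, with a prior count, the log2 changes in innate lymphoid cell 2-like cells were 9.08 for Mt1, 5.57 for Mt2 and 4.82 for Cxcl2. Cxcl2 was far more abundant in neutrophil-like cells after LPS. Whether Cxcl2 transcripts in gamma-delta T cell-like and innate lymphoid cell 2-like cells were those cells' own was not tested. Gzma was at least 95.2-fold higher, at 673 CPM in LPS library 1 but 12.7 CPM in LPS library 2. Podnl1 was at least 16.2-fold and Jchain at least 12.8-fold lower, and the lipid-carrier gene Apoe (-6.10; 18.4 and 10.2 CPM after LPS) and Cxcr6 (-4.59) fell.

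Precursor B cell-like cells (367 control, 157 and 117 LPS cells) had interferon-induced genes at higher levels, with Iigp1 299-fold and Serpina3g 72.6-fold higher (175 and 269 CPM), a Serpina3f ratio of 379 (129 to 1841; 246 and 373 CPM) and 18 of 18 interferon genes called. Saa3 rose 490-fold but lay at 47.6 CPM in LPS library 1 and 951 CPM in LPS library 2. The macrophage genes Apoe (log2 -3.91), C1qa (-2.95; 9.29 and 4.44 CPM after LPS) and C1qb (-2.32; 7.54 and 16.6 CPM) fell, as did Cebpg (-1.97). The class spanned clusters 16 (155 control, 91 and 58 LPS cells), 20 (163, 55 and 52) and 33 (49, 11 and 7). The share of border-associated macrophage-like cells also fell, from 18.0% to 4.04% and 2.86%. Whether the Apoe, C1qa and C1qb transcripts in precursor B cell-like cells were those cells' own was not tested. The same holds for Apoe in innate lymphoid cell 2-like cells. Plasmacytoid dendritic cell-like cells (58 control, 31 and 60 LPS cells) had at least 49.9-fold higher AA467197 (217 and 429 CPM), at least 24.6-fold higher Saa3 (61.3 and 256 CPM), at least 14.3-fold higher Slc4a8 (44.9 and 140 CPM) and at least 8.83-fold higher Gpnmb. AA467197 stood at 2636 and 2401 CPM in classical monocyte-like cells after LPS, and Saa3 at 19289 and 38532 CPM in border-associated macrophage-like cells. Genes that fell were Lyz2 (-5.22), Ccr2 (-3.38), Clec12a (-3.30) and Cd209a (-3.25). Cd209a is a marker of conventional dendritic cell 2-like cells, whose share fell from 5.40% to 0.637% and 0.212%. Whether these transcripts in plasmacytoid dendritic cell-like cells were those cells' own was not tested. Lyz2 stood at 968 CPM in control and 4.09 CPM (1 UMI) and 39.6 CPM after LPS, Ccr2 at 36.8 and 11.7 CPM and Clec12a at 65.4 and 32.6 CPM. Without LPS library 1, with a prior count, the log2 change of Lyz2 in plasmacytoid dendritic cell-like cells was -4.47, and without LPS library 2 it was -6.64 for Lyz2, -2.45 for Ccr2 in plasmacytoid dendritic cell-like cells and -2.69 for Clec12a. Neutrophil genes rose in these classes as well: 4 of 5 in NK cell-like (mean log2 2.84), 4 of 6 in T cell-like (3.29), 3 of 3 in gamma-delta T cell-like (2.62), 1 of 3 in innate lymphoid cell 2-like (1.93) and 3 of 5 in precursor B cell-like cells (2.28). In plasmacytoid dendritic cell-like cells 6 of 7 rose over the list alone (5.88). B cell genes fell: 3 of 5 in NK cell-like (mean log2 -1.12), 3 of 5 in T cell-like (-2.71) and 2 of 4 in innate lymphoid cell 2-like cells (-5.12). In control T cell-like cells, 1 cell held 99.4% of 10618 Igkc UMIs and 1 cell held 99.8% of 6160 Igha UMIs. A fall of these immunoglobulin genes in T cell-like cells therefore rests on 1 control cell for each gene. Counts of genes that rose and fell were 877 and 720 in NK cell-like, 747 and 546 in T cell-like, 341 and 216 in gamma-delta T cell-like, 351 and 233 in innate lymphoid cell 2-like, 665 and 399 in precursor B cell-like and 52 and 34 in plasmacytoid dendritic cell-like cells. With no cell filter, 41 rose and 0 fell in precursor B cell-like cells (edgeR, 1650 at an unadjusted p under 0.05; DESeq2 with the filter 179 and 23), and without doublet removal 108 and 31 in gamma-delta T cell-like cells. Without TMM they were 596 and 909, 630 and 954, 183 and 176, 335 and 283, 425 and 875, and 226 and 201 in the same order. In the other cell classes LPS vs control, the total of called genes was 10718, against 3494 with cells thinned to 1000 UMIs and 5098 with DESeq2. In gamma-delta T cell-like and precursor B cell-like cells the edgeR fit gave all genes 1 shared spread. A gene whose LPS libraries differ, such as Saa3 in precursor B cell-like cells, therefore has a p-value that understates that difference. The spread was mostly shared too in innate lymphoid cell 2-like, NK cell-like and T cell-like cells (prior degrees of freedom 68.2, 34.3 and 32.9, against 1 residual). The p-values of Gzma in innate lymphoid cell 2-like cells and of Il10 in NK cell-like cells carry a similar limit.

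Il10 itself was called higher in NK cell-like, T cell-like and neutrophil-like cells. NK cell-like cells had 0 Il10 UMIs in the control library and 13.3 and 22.9 CPM in the LPS libraries, at least 12.9-fold higher (adjusted p = 2.9e-06, edgeR). At least 1 Il10 UMI was found in 20 of 402 NK cell-like cells of LPS library 1 (4.98%, exact 95% interval 3.07 to 7.58%) and in 42 of 497 of LPS library 2 (8.45%, 6.16 to 11.3%), against 0 of 336 control cells, which allows a share of up to 0.893%. Thinned to 1000 UMIs, the shares were 2.49% and 2.22%. T cell-like cells were at least 8.14-fold higher (adjusted p = 0.00174), with UMIs in 6 of 380 (1.58%) and 16 of 534 cells (3.00%). Neutrophil-like cells were at least 6.93-fold higher (adjusted p = 0.0423), with UMIs in 10 of 282 (3.55%) and 26 of 425 cells (6.12%). Immature cells of cluster 22 made up 74 of the 80 control neutrophil-like cells, but 91 of 282 and 91 of 425 LPS cells. This call thus also compares cells of unlike maturity. NK cell-like cells held 29.8% and 23.6% of all Il10 UMIs of the LPS libraries. As background, gamma-delta T cell-like cells had 0 Il10 UMIs in 150 and 97 LPS cells, which allows up to 2.0% and 3.09%, at median depths of 4872.5 and 4819 UMIs against 5090 and 4288 in NK cell-like cells. The T cell-like shares lie within what this background allows in both LPS libraries, and the NK cell-like shares above it. Neutrophil-like shares, taken without their intervals, lie above it, but at median depths of 9828.5 and 8184 UMIs, and were 0.712% and 1.19% when thinned.

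In microglia-like cells Il10 was near or below detection: 2 of 464 cells in LPS library 1 (0.431%, 0.0522 to 1.55%), 0 of 534 in LPS library 2 (up to 0.562%) and 0 of 560 control cells (up to 0.536%). Border-associated macrophage-like cells held 66.7% of the control library's Il10 UMIs, in 4 of 804 cells (0.498%), and had Il10 UMIs in 4 of 146 (2.74%) and 5 of 162 LPS cells (3.09%), a log2 change of 2.88 (SE 0.96) that did not pass (adjusted p = 0.144). The 66.7% thus rests on 4 cells, in a class that made up 18.0% of control cells. The receptor genes Il10ra and Il10rb were present in microglia-like cells at 224 and 217 CPM in the control library; Il10ra stood at 143 and 118 CPM (log2 -0.78, SE 0.25, adjusted p = 0.134) and Il10rb at 102 and 120 CPM (-0.97, SE 0.24, adjusted p = 0.092) after LPS. Il10ra rose in innate lymphoid cell 2-like (2.05), neutrophil-like (1.56), NK cell-like (1.45) and T cell-like cells (1.02) and fell in classical monocyte-like cells (-1.07). Il10rb rose in neutrophil-like cells (1.59) and fell in precursor B cell-like (-1.43), NK cell-like (-1.06) and T cell-like cells (-0.99).

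Socs3, a feedback inhibitor of cytokine signalling induced through STAT3, rose in microglia-like cells from 22.8 to 255 and 388 CPM (log2 3.81, SE 0.42, adjusted p = 0.0494) and in border-associated macrophage-like cells 72.4-fold (log2 6.16, SE 0.40, adjusted p = 0.0149). It also rose in neutrophil-like (5.06), NK cell-like (4.83), classical monocyte-like (4.52), T cell-like (3.45), gamma-delta T cell-like (3.17) and non-classical monocyte-like cells (2.69). It was at least 91.0-fold higher in granulocyte-monocyte progenitor-like and at least 38.7-fold higher in innate lymphoid cell 2-like cells, and did not pass in plasmacytoid dendritic cell-like cells (2.51, adjusted p = 0.181). Stat3 stood at 88.2, 274 and 224 CPM in microglia-like cells (2.82-fold, SE of log2 0.28, adjusted p = 0.0685), Il6 at 7.61, 5.37 and 4.04 CPM (adjusted p = 0.388) and the endotoxin receptor gene Tlr4 at 51.9, 30.4 and 19.3 CPM (adjusted p = 0.137). By GENCODE annotation of GRCm38, Il10 lies on chromosome 1 at 131019845 to 131024974 on the plus strand, Il10ra on chromosome 9 at 45253837 to 45269149 and Socs3 on chromosome 11 at 117966079 to 117970047, both on the minus strand. Il10rb lies on chromosome 16 at 91406164 to 91425834 on the plus strand.

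**Figure D4:**
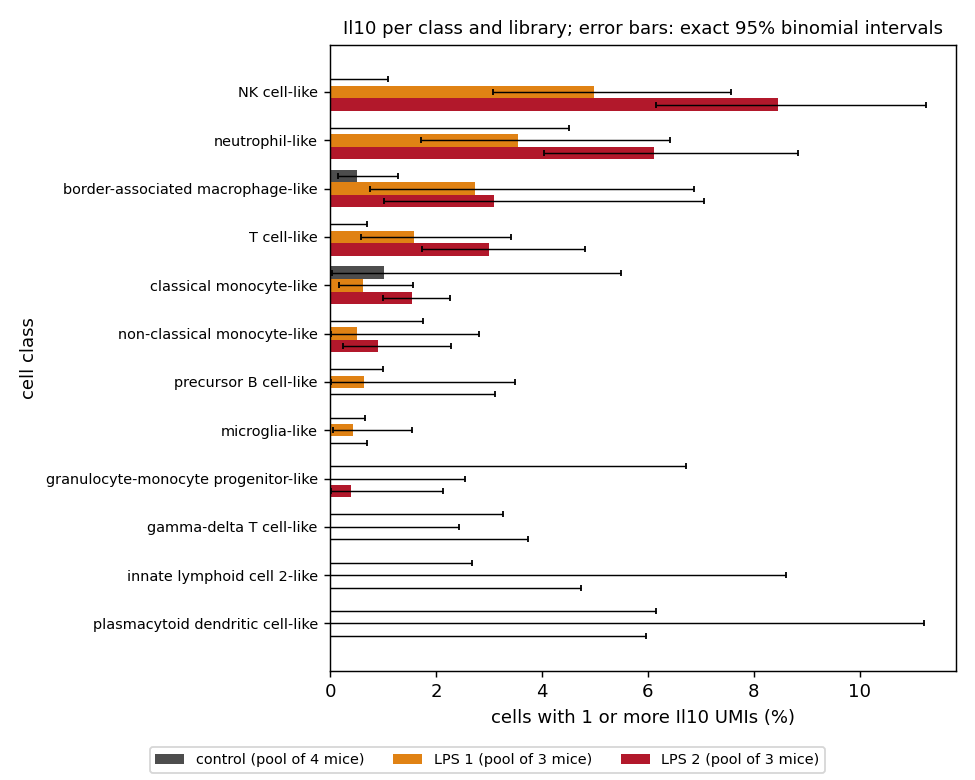
Share of cells with 1 or more Il10 UMIs (%, horizontal axis) in each class with at least 30 cells in each library, per library (bars), with exact 95% binomial intervals as error bars. NK cell-like cells had 0% in the control library and 4.98% and 8.45% in the LPS libraries, and gamma-delta T cell-like cells had 0% in each library.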

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

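Chosen only after the result was seen were the tests of shared barcodes, of the makeup of control-type cells, and both tests of microglia-like rises against markers that control microglia-like cells lack.

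The LPS change differed between border-associated macrophage-like and microglia-like cells for 264 genes in an edgeR test of the difference itself, with 1 control and 2 LPS libraries per class. Larger changes in border-associated macrophage-like cells, as log2 differences, were found for Bcl2a1a, an anti-apoptotic gene (6.51, SE 0.75, adjusted p = 0.00102), Edn1, of the vasoconstrictor endothelin (5.56, SE 1.03, adjusted p = 0.0149), Ttc39c (5.53, SE 1.32, adjusted p = 0.0478), Plpp1 (4.63, SE 0.79, adjusted p = 0.00857) and Il1a (4.59, SE 0.54, adjusted p = 0.0012). Higher log2 changes in microglia-like cells were found for Ahr, the aryl hydrocarbon receptor (-5.68, SE 0.59, adjusted p = 0.000817), Gpr65 (-5.21, SE 0.34, adjusted p = 1.71e-05), Fam43a (-4.83, SE 1.09, adjusted p = 0.037), the scavenger receptor gene Msr1 (-4.08, SE 0.56, adjusted p = 0.00243) and Slfn5 (-3.67, SE 0.41, adjusted p = 0.00102). Edn1, Bcl2a1a, Ttc39c and Il1a rested on 0.208, 0.416, 0.624 and 0.832 CPM in control border-associated macrophage-like cells. The LPS libraries of that class stood apart for Ttc39c (15.3 and 177 CPM) and Plpp1 (13 and 115 CPM). In microglia-like cells Ttc39c was also low, at 1.04 CPM in control and 0.447 and 6.29 CPM after LPS. Ahr rested on 1.04 CPM in control microglia-like cells, and Fam43a was too low there for a test of its own. In border-associated macrophage-like cells Fam43a fell from 62.2 to 18.4 and 6.12 CPM (log2 -2.28). Its difference is therefore not shown to be a larger change in microglia-like cells.

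Il10 was also seen in cells that no comparison used. In unnamed cluster 21, led by Jchain, Igha and haemoglobin genes, it was found in 3 of 49 cells of LPS library 1 (6.12%, exact 95% interval 1.28 to 16.9%) and 5 of 75 of LPS library 2 (6.67%, 2.20 to 14.9%), against 1 of 133 control cells (0.752%, 0.0190 to 4.12%). In unnamed cluster 32, with markers of neutrophils and non-classical monocytes, it was found in 7 of 63 (11.1%, 4.59 to 21.6%) and 4 of 41 cells (9.76%, 2.72 to 23.1%), and the cluster held no control cells. Cells were deep in cluster 32 (medians of 16749 and 16066 UMIs) and shallower in cluster 21 (4508 and 4023 UMIs). Thinned to 1000 UMIs, the shares were 1.59% and 2.44% in cluster 32 and 2.04% and 1.33% in cluster 21, each from 1 cell. As background, unnamed cluster 24, at 18082 and 14950 UMIs, had Il10 UMIs in 0 of 53 and 0 of 90 cells, which allows up to 5.66% and 3.33%, and gamma-delta T cell-like cells allow up to 2.0% and 3.09% at 4872.5 and 4819 UMIs. The intervals of both clusters reach below these limits, so free RNA is not excluded as a source of this Il10. The intervals cover counting error only.

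In LPS library 1, 373 of 3611 cells lay in clusters made up mostly of control cells, against 62 of 5665 in LPS library 2. None of the 373 barcodes was also called in the control library (upper 95% limit 0.984%), which argues against barcodes shared between the libraries. The makeup of these cells over 11 control-type clusters differed from that of the control library (chi-square 100.4, 10 degrees of freedom, p = 4.51e-17), with 60 cells of non-classical monocyte cluster 19 against 24.0 from the control makeup, which argues against control cells carried over as the whole cause. Among microglia-like cells of LPS library 1, those in the control-type cluster had 0.987 times the median UMIs of the others (4588 and 4648), which argues against shallow cells. In microglia cluster 5, P2ry12 stood at 1223 CPM in LPS library 1 and 3109 CPM in control (without TMM). Ifitm3 stood at 306 and 47.0 CPM there, and Lcn2 at 547 and 5.22 CPM. Ccl5 (43.7 and 48.9 CPM) and Sdc4 (35.0 and 25.4 CPM) differed little, and no test was run on these values. A mouse in the pool of LPS library 1 that took up less LPS or responded less remains open. It was not tested, as the labels do not assign cells to mice.

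Saa3 and Lcn2 UMIs were found in lymphocytes of the LPS libraries, for Saa3 in 31.8% of NK cell-like and 28.9% of T cell-like cells of LPS library 1 and in 43.7% and 43.6% of LPS library 2. If they came from one pool of free RNA, the ratio of cells with Saa3 to cells with Lcn2 would be alike in NK, T, gamma-delta T and innate lymphoid cell 2-like cells, and no difference was found (chi-square p = 0.821 in LPS library 1 and p = 0.239 in LPS library 2). This is consistent with free RNA as a source of Saa3 and Lcn2 in these classes, although a p-value that misses the threshold does not show equal ratios, and the rise of Saa3 in lymphocyte classes may not be their own. In LPS library 2, cells with Saa3 and with Lcn2 numbered 217 and 118 (NK cell-like) and 233 and 140 (T cell-like). They numbered 40 and 29 in gamma-delta T cell-like and 26 and 25 in innate lymphoid cell 2-like cells. A cell with both transcripts enters both numbers, so the counts behind the chi-square test are not independent. No biological explanation was tested.

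For the 118 genes called higher in microglia-like cells, free RNA of neutrophils and classical monocytes was weighed by the ratio of microglia-like CPM to library-wide CPM. By the test set beforehand, 48 genes (40.7%) exceeded the highest marker ratio in both LPS libraries, a share under 50%, which by that test's own rule falls on the side of free RNA. That reading was set aside only after the result was seen, because the highest ratio came from Csf3r (1.30 and 1.13), which control microglia-like cells carry at 294 CPM, so the bound reflects their own transcripts. Against markers under 5 CPM in control microglia-like cells, 101 genes (85.6%) lay above the highest marker ratio in both LPS libraries, short of the 90% set for all 118. The lower quartile of the 118 ratios was still at least 1.67 times that highest ratio, and their median was 0.877 and 0.930 against 0.0343 and 0.0124 for these markers. Most of the 118 thus stood above what the ratios of these markers would give. This criterion was also set after the preset result was seen, and the 118 genes were picked for their rise in these cells. It is weaker evidence than a preset test and does not exclude free RNA as a source. For the 17 genes not above that highest marker ratio, among them Lcn2, AA467197, Isg15, Irf7 and Rsad2, free RNA could be a source and stays open.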

How the results depend on the processing

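Chosen only after the result was seen were the adjusted p under 0.1 and the fit of immature neutrophil-like cells alone. Except where a table or the setting's own construction is named, the cause was not tested. No paired analysis was possible because there is only 1 control library.

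The count of called genes depended on the processing. For microglia LPS vs control, 172 genes were called, against 732 with DESeq2, 5 with limma-voom, 1379 with no TMM, 2129 with no cell filter, 2172 at 5% mitochondrial UMIs, 1703 with no doublet removal, 1600 at Leiden resolution 2, 2312 with each library clustered alone, 1143 with cells thinned to 1000 UMIs, 2032 with the library profile subtracted and 1446 at an adjusted p under 0.1. edgeR called 0 with no count filter (2499 at an unadjusted p under 0.05) and 0 at Leiden resolution 0.5 (2796 at an unadjusted p under 0.05), where limma-voom on the unaltered classes called 5 and DESeq2 732. Many adjusted p-values lie just under or just over 0.05, which the count of 1446 at 0.1 shows. Of the 172 genes, DESeq2 called 171 in the same direction, no TMM 172, clustering each library alone 172 and thinning 164. At Leiden resolution 2, 1 of 171 tested went the other way, and with no cell filter 113 of 1337 tested neutrophil-like calls did.

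For border-associated macrophage LPS vs control, 336 genes were called, against 633 with DESeq2, 2016 with limma-voom, 1637 with no TMM, 2123 with no count filter, 1913 with no cell filter, 2045 at 5% mitochondrial UMIs, 1699 with no doublet removal, 861 with each library clustered alone, 641 with cells thinned to 1000 UMIs and 1580 with the library profile subtracted. It was 337 at Leiden resolution 0.5 and 336 at Leiden resolution 2. For other cell classes LPS vs control, 10718 calls became 5098 with DESeq2 and 3494 with cells thinned to 1000 UMIs, which tests fewer genes. Classes too small under a setting dropped out of it: 7 of these 10 classes were left with 5% mitochondrial UMIs or less (9475 calls against 8984 in the same classes), 8 with no doublet removal (11322 against 8654), 8 at Leiden resolution 0.5 (11720 against 8654) and 9 with each library clustered alone (11239 against 9654). Classical monocyte-like cells were not tested with no doublet removal or at Leiden resolution 0.5. Over the classes tested, settings other than DESeq2 and thinning moved the total by less than 1.5 times; subtracting the library profile was not run on these classes. Single classes moved further: precursor B cell-like from 1064 to between 41 (no cell filter) and 1300 (no TMM), gamma-delta T cell-like from 557 to between 139 (no doublet removal) and 644 (no cell filter), and neutrophil-like from 1439 to between 209 (thinned) and 3883 (no doublet removal). Granulocyte-monocyte progenitor-like calls went from 2017 to between 266 (thinned) and 3155 (no count filter), classical monocyte-like from 1978 to between 832 and 2715 under the same settings, innate lymphoid cell 2-like from 584 to between 158 (thinned) and 641 (no cell filter), NK cell-like from 1597 to between 377 (DESeq2) and 1806 (Leiden resolution 0.5), T cell-like from 1293 to between 405 (DESeq2) and 1584 (no TMM), and plasmacytoid dendritic cell-like from 86 to between 56 (DESeq2) and 427 (no TMM). Non-classical monocyte-like calls went from 103 to between 0 in edgeR with no TMM (1786 at an unadjusted p under 0.05, 311 by DESeq2 and 111 by limma-voom) and 1244 (no count filter). In the microglia against border-associated macrophage response, 264 genes became 547 with no count filter, 566 with no doublet removal and 462 at Leiden resolution 2, and 290 with no TMM.

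Of 19 cell class shares LPS vs control 7 passed, against 13 of 17 at 5% mitochondrial UMIs, 4 with each library clustered alone (1 of the 7, migratory dendritic cell-like) and 0 of 20 at Leiden resolution 2. There were 8 with no cell filter, 7 with no doublet removal, 6 at Leiden resolution 0.5, 7 with TMM over classes and 5 without neutrophil-like cells. Log2 changes of the 7 ranged over these settings from 2.71 to 12.95 for classical monocyte-like cells (0 control cells with no doublet removal), from -1.59 to -4.06 for B cell-like, from -1.09 to -3.72 for conventional dendritic cell 2-like, from -2.24 to -2.69 for border-associated macrophage-like, from 1.63 to 3.58 for neutrophil-like, from 3.49 to 4.40 for migratory dendritic cell-like and from 0.80 to 2.15 for granulocyte-monocyte progenitor-like cells. In gene lists LPS vs control for microglia-like cells, 15 lists passed camera, against 0 in camera with an estimated correlation and 0 in fry. List members called in microglia went from 51 to 139 when adjusted over the list alone. The mean share of NK cell-like cells with Il10 in the LPS libraries (the IL-10 axis across cell classes) was 6.71%, and 2.36% with cells thinned to 1000 UMIs, as fewer UMIs per cell find fewer Il10 molecules. In the agreement of the 2 LPS libraries, the SD of 0.531 in microglia-like cells became 0.593 with no count filter. With no cell filter, Mgl2 in neutrophil-like cells went to a log2 change of 0.40 (adjusted p = 0.918) and Elane in neutrophil-like cells to 1.69 (adjusted p = 0.377), from falls.

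Leaving out an LPS library leaves 1 library against 1, so folds but no test and no count can be given. Of the gene and class pairs named by rank, 55 moved and 60 did not without LPS library 1. Without LPS library 2, 68 moved and 46 did not. A move is a shift by more than the SD between the LPS libraries. The values without a library carry a prior count of 2, which the main folds do not. Genes with 0 or few control counts can therefore move for that reason alone. These pairs were chosen with both LPS libraries on the same side of the control, so their directions were fixed by that choice. Depth limits the detection of Il10, as the thinned shares show.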

Other observations

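All values in this part were chosen for report after the data were read, and no test was run on them. Among cells outside the named classes, unnamed cluster 14, led by Cxcl9, Cxcl13 and MHC class II genes, held 5 control cells and 121 and 238 LPS cells. Unnamed cluster 17, led by MHC class II genes, Axl and Ccr2, held 262 control cells and 35 and 2 LPS cells. Migratory dendritic cell-like cells, too few in the control library (12 cells) for a test of genes, had Il10 UMIs in 5 of 132 (3.79%, exact 95% interval 1.24 to 8.62%) and 3 of 279 LPS cells (1.08%, 0.222 to 3.11%), at median depths of 13868 and 11264 UMIs. Both shares lie within the 5.66% and 3.33% that 0 of 53 and 0 of 90 cells of unnamed cluster 24 allow, at 18082 and 14950 UMIs. These intervals cover counting error only.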
